A study of Mus musculus with 4 samples.

How the data were processed

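Gene expression was measured with Illumina bead arrays on total RNA from sorted mouse peritoneal macrophages, with 1 array per sample. Per the labels, 2 samples came from control mice and 2 from Mac-Gata6 KO mice, which carry a floxed Gata6 and Cre recombinase expressed from the lysozyme M locus. All 4 samples were untreated, of strain C57BL/6, and from animals 8 to 16 weeks old. RNA was extracted on spin columns with a DNase step and biotin-labelled cRNA was prepared for the arrays, per the labels' protocols. The labels do not say whether the controls carried Cre, or whether replicates came from separate animals or pools, so p-values measure only the spread between these samples, which may be technical.

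The authors deposited a table of probe intensity values that were not normalized, with a detection p-value for each probe and array, per the file headers. A second deposited table holds the authors' processed intensity values on a linear scale. Its columns shared 1 distribution (medians between 142.05 and 142.14), had not been centred, and ranked the probes of each array as the first table did. The software that read the arrays and made either table is not given in the sources used here. Probes numbered 45281. Blank lines at the end of the first table (1349) were dropped, and no column of per-sample values was left unused.

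Intensities were corrected for background and normalized with neqc of limma 3.58.1 in R 4.3.3. This fits the background from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A probe was kept when its detection p-value was under 0.05 on at least 2 arrays, which left 16713 probes. The platform annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10378. Of the annotated probes, 34807 matched the RefSeq table of assembly GRCm38.p6 by gene identifier, and no symbol changed. Each gene was represented by its probe with the highest mean over the 4 arrays, and a probe with no symbol stood for itself. This gave 9200 genes with a symbol and 2428 unnamed probes, 11628 in all, called genes below. Probes of closely related family members can bind each other's transcripts, so values of the Ear, Gstp, Cd209, Bcl2a1, class II and globin families are uncertain as to the member.

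Between 35.5% and 36.4% of the probes were detected on each array, and median raw intensity lay between 136 and 146. The number of arrays limits the precision. Where a probe was not detected on either array of a group, only a bound is given for its change. Its fitted values still enter the tests, list medians, figures and, said as fitted, comparisons between settings or probes. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among detected probes. Such a probe is described as not well above background. A bound holds for the main normalization only, since fold sizes depend on the background correction.

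Mac-Gata6 KO was compared with control by lmFit and eBayes of limma with 1 coefficient and no block. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Errors after ± are standard errors of the fit unless SD is given. Gene lists, 28 in number, were tested with camera of limma at its preset inter-gene correlation of 0.01 when at least 5 members were measured, with Benjamini-Hochberg adjustment over the lists. Camera was also run with the correlation estimated from the data. Both procedures were tested on simulated data for this comparison with the levels and spread of the 11628 genes. Of 100 genes changed by 1 on the log2 scale 45% were recovered, and of 100 changed by 2, 98%, with 7 unchanged genes called. The changed genes were a far smaller share than the 12.3% called in the data, so the adjusted threshold was stricter in the simulation. These recovery rates therefore do not carry over directly to the data. In 20 simulations with no change no list was called. Noise was drawn independently for each gene, so these runs do not test list calls where members vary together.

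The tests of the comparison and of the lists, the lists themselves, the rule for named genes and all alternatives but 1 were fixed before the data were examined. Some tests of possible explanations were chosen later, as stated with them. Named genes were Gata6, the 15 called genes with the largest change in each direction whose knockout arrays both lay on the same side of both control arrays, and up to 4 members with the smallest unadjusted p of each list described. Probes with no symbol, RIKEN clone names and predicted genes were counted but not named. Further genes are said to have been chosen after their values were seen. Alternatives covered the background correction, the offset, the scaling, the authors' values, the detection filter, the probes per gene, the variance model, the replicate number as a block, leaving out each array, a fold threshold and the estimated correlation. A block for the slide was not run, since the headers name no slide.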

Results

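Whole-genome expression was measured in sorted peritoneal macrophages from mice labelled control and mice labelled Mac-Gata6 KO, with 2 arrays per group. The series asks which genes depend on the transcription factor GATA6 in these cells. Detected probes numbered 16380 and 16096 on the control arrays and 16484 and 16140 on the Mac-Gata6 KO arrays. The median absolute difference between arrays over the 11628 genes was 0.16 on the log2 scale within control and 0.18 within knockout, against 0.26 to 0.30 between groups.

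Gata6 itself was lower in the knockout. Its signal was 13.77 and 13.66 on the control arrays and 13.07 and 12.83 on the knockout arrays (log2 normalized intensity). The fitted log2 change was -0.76 ± 0.15 (adjusted p = 0.0270), which leaves 59.0% of the control signal. A second, dim Gata6 probe was detected on both control arrays and on neither knockout array, and was at least 1.74-fold lower. Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so the signal does not by itself check the labels. With any 1 array left out the Gata6 change no longer passed, at log2 changes from -0.91 to -0.63.

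In the knockout, 711 genes were higher and 714 lower than in control, together 12.3% of those tested. Of these, 372 were higher and 332 lower by at least 2-fold. The counts at 2-fold were 167 and 154 without background correction and 175 and 163 with the authors' values. Among the called genes, 137 higher and 184 lower ones were probes with no gene name. Another detected probe was present for 402 called genes and pointed the opposite way for 38. Leaving out 1 array lowered the counts by more than 1.5 times. They were 390 higher and 238 lower without control 1, 389 and 249 without control 2, 249 and 332 without knockout 1, and 313 and 416 without knockout 2.

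The genes that fell most included several with high signal in control macrophages. Nt5e, the ectonucleotidase that makes adenosine, fell by 7.06 ± 0.16 on the log2 scale, from 13.41 ± 0.17 to 6.35 ± 0.13 (SD, n = 2 arrays per group). Its second probe was not well above background in the knockout and at least 68.6-fold lower. Ltbp1, which encodes a latent TGF-beta binding protein, was at least 163-fold lower and not well above background in the knockout. That bound holds for the main normalization. The fitted log2 change of this probe was -7.90 there, -5.79 without background correction and -5.94 with the authors' values. A second Ltbp1 probe, designed to another transcript record and dim in both groups, had a log2 change of -0.28 ± 0.40 and did not pass. Without control 1 or without control 2 the bright probe was detected on too few arrays to be kept, and the dim one took its place and did not pass. The log2 changes were -6.22 ± 0.14 for Garnl3, -5.30 ± 0.13 for Itga6, a laminin-binding integrin subunit, -4.89 ± 0.14 for prostacyclin synthase Ptgis and -4.87 ± 0.15 for Serpinb2, an inhibitor of plasminogen activators. Hdc, the enzyme that makes histamine, changed by -4.32 ± 0.18, Sel1l3 by -4.17 ± 0.16, Ipcef1 by -3.84 ± 0.16 and the serine protease Htra3 by -3.77 ± 0.18. Hdc and Sel1l3 were detected on 1 of the 2 knockout arrays. Not well above background in the knockout were Shank3 (at least 15.05-fold lower), Vmn2r26 (15.2), Egln3 (9.33), Srgap3 (8.79) and She (7.55). Adjusted p for these 15 genes was at most 0.00028.

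Among the genes that rose most, Fcrls, an Fc receptor-like gene, rose by 5.25 ± 0.19 on the log2 scale, from 6.49 ± 0.30 to 11.74 ± 0.17 (SD, n = 2 arrays per group). Folate receptor Folr2 rose from 10.11 to 14.46, a change of 4.35 ± 0.14, and mannose receptor Mrc1 from 9.97 to 13.96, a change of 3.99 ± 0.13. Gas6, a ligand of receptor kinases that take part in uptake of dying cells, rose by 4.92 ± 0.15. Fxyd2 rose by 4.67 ± 0.22, the leukotriene receptor Ltb4r1 by 3.52 ± 0.15, the class II gene H2-Eb1 by 3.42 ± 0.15 and the hyaluronan receptor Lyve1 by 3.17 ± 0.18. Ear3 (5.03 ± 0.14) and Gstp2 (3.47 ± 0.15) belong to families of similar sequence. The other Ear3 probes were not well above background in control and at least 1.49-fold and 2.005-fold higher. Not well above background in control were Cd209f (at least 30.9-fold higher), Hr (15.51), Tmod1 (8.99), Akr1c18 (7.80) and Pcolce2 (5.34). Adjusted p for these 15 genes was at most 0.00031.

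**Figure D1:**
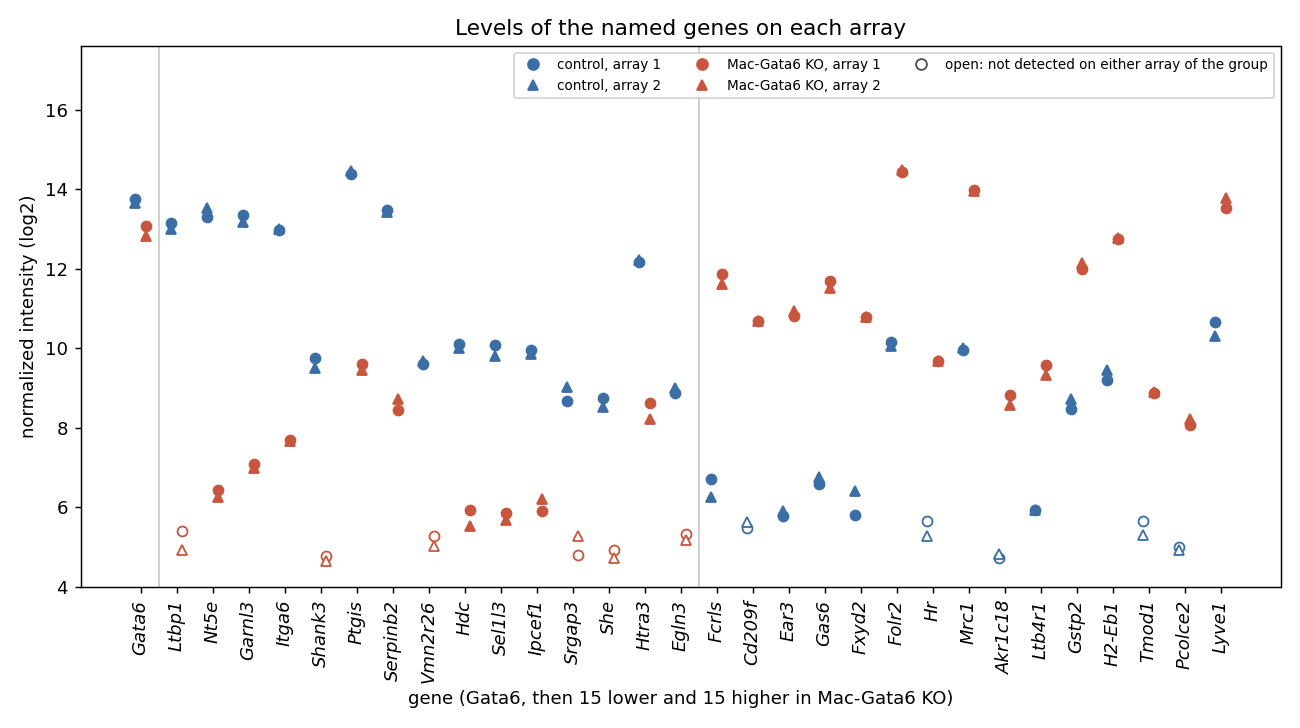
Log2 normalized intensity on each array (vertical axis) for Gata6 and for the 15 named genes lower and the 15 higher in Mac-Gata6 KO (horizontal axis), with circles and triangles for arrays 1 and 2 of a group and open symbols where neither array of a group detected the probe. Gata6 has a log2 change of -0.76, while the fitted log2 changes reach from -7.06 to -3.77 for the 9 lower genes and from 3.17 to 5.25 for the 10 higher genes detected in both groups.

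Genes known from large peritoneal macrophages fell as a list. Of 33 measured members 20 fell, none rose and 13 did not pass, with the same 20 adjusted over the list alone, and the median log2 change was -0.94. Nt5e, Garnl3, Itga6 and Ltbp1, given above, had the smallest p. The camera test gave an adjusted p of 6.3e-15, and adjusted p = 0.235 with an estimated correlation. Part of this list may have been described as GATA6-dependent on these same samples, so its fall is not independent evidence. Other members did not pass. Chosen after its value was seen, the uptake receptor Timd4 had a log2 change of -0.08 ± 0.17.

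Genes known from small peritoneal macrophages rose as a list. Of 14 measured members 10 rose, none fell and 4 did not pass, with 11 risen adjusted over the list alone. The median log2 change was 1.35, or 1.22 with genes not well above background at their bound. Folr2, Mrc1, Fcrls and Lyve1 had the smallest p. Camera gave an adjusted p of 2.9e-10, and adjusted p = 0.235 with an estimated correlation.

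Genes of class II antigen presentation rose, 7 of 14 with none fallen, and 11 adjusted over the list alone. H2-Eb1 was joined by H2-Aa (2.92 ± 0.15), H2-Ab1 (2.89 ± 0.14) and the invariant chain Cd74 (2.49 ± 0.14). Camera gave an adjusted p of 2.2e-07, and adjusted p = 0.235 with an estimated correlation. B cells also express these genes, and the B cell list moved the same way. Of its 14 measured members 7 rose, none fell, and 8 rose adjusted over the list alone (camera adjusted p = 0.00018, and adjusted p = 0.235 with an estimated correlation). Fcrla rose by 1.69 ± 0.14, Pou2af1 by 1.39 ± 0.17, Blk by 1.12 ± 0.13 and Fcmr by 1.04 ± 0.13. Fcrla did not pass without knockout 1 or without knockout 2.

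Genes typical of macrophages of other tissues rose as a list, 5 of 9 measured with 1 fallen, and 6 and 2 adjusted over the list alone. Camera gave an adjusted p of 0.0011, and adjusted p = 0.237 with an estimated correlation. The array held 24 of these genes, and those that failed the detection filter were not tested. The haptoglobin-haemoglobin receptor Cd163 rose by 2.98 ± 0.14. In the main normalization the nuclear receptor Pparg was at least 3.60-fold and Gpr34 at least 2.60-fold higher, and Fabp5 was at least 2.50-fold lower. Pparg and Gpr34 passed the detection filter only through the knockout arrays, and Fabp5 only through the control arrays. Genes of alternative activation went both ways, with 6 risen and 4 fallen of 20, and 10 and 4 adjusted over the list alone. Of these, 5 of the 6 risen and 2 of the 4 fallen are also members of another list that passed. Camera gave an adjusted p of 0.0115 upwards, and adjusted p = 0.358 with an estimated correlation. Beside Mrc1 and Pparg, transferrin receptor Tfrc rose by 1.87 ± 0.16, while the lipoxygenase Alox15 fell by 1.27 ± 0.15. The list of immediate early and heat shock genes was higher, with 7 of 23 risen and 1 fallen, and 7 and 2 adjusted over the list alone (camera adjusted p = 0.0061, and adjusted p = 0.237 with an estimated correlation). Egr2 rose by 2.65 ± 0.14, Jun by 1.53 ± 0.19, Egr1 by 1.48 ± 0.16 and Jund by 1.34 ± 0.17. None of the 7 measured heat shock genes passed. With 1 array left out some of these lists did not pass. The list of other tissues had an adjusted p of 0.242 without knockout 1 and 0.0745 without knockout 2, alternative activation 0.122 without knockout 2, and the immediate early list 0.0666 without knockout 1.

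Cell cycle genes were lower as a list, yet few members passed. Of 36 measured, 2 fell and 1 rose, with 1 and 1 adjusted over the list alone, and 31 had a negative log2 change (median -0.38). Top2a changed by -0.74 ± 0.17 and Tk1 by -0.68 ± 0.13. Kif23 rose by 1.14 ± 0.14, though another of its probes went the opposite way, and Aurka had a log2 change of -0.57 ± 0.15 (adjusted p = 0.0592) and passed in 5 alternative settings. Camera gave an adjusted p of 0.00044, and adjusted p = 0.235 with an estimated correlation. Integrins were lower as a list, with 3 fallen and 1 risen of 12, and 5 and 2 adjusted over the list alone. Camera gave an adjusted p of 0.040, and adjusted p = 0.351 with an estimated correlation. By far the largest fall was that of Itga6 (log2 change -5.30), which is also on the peritoneal macrophage list, so the integrin result is not separate from that list. Beside Itga6, Itgb7 changed by -1.62 ± 0.14 and Itgb1 by -0.79 ± 0.13, and Itgb5 was at least 1.30-fold higher. Without knockout 2 the integrin list had an adjusted p of 0.052. Top2a, Tk1 and Itgb1 did not pass with any 1 array left out, nor Itgb5 without either control. With the replicate number as a block Top2a and Tk1 did not pass either, nor Top2a with no detection filter or Tk1 with median scaling.

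Erythroid genes rose as a list, 3 of 5 measured with none fallen, and 4 adjusted over the list alone. Camera gave an adjusted p of 0.00052, and adjusted p = 0.237 with an estimated correlation. The array held 12 of these genes, and those that failed the detection filter were not tested. Globin genes Hbb-bs and Hba-a1 were not well above background in control and at least 5.72-fold and 5.11-fold higher in the knockout. Their probes passed the detection filter only through the knockout arrays. Hbb-bt, detected on all 4 arrays, rose by 1.74 ± 0.18, and Klf1 had a log2 change of 0.60 ± 0.19, which did not pass.

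**Figure D2:**
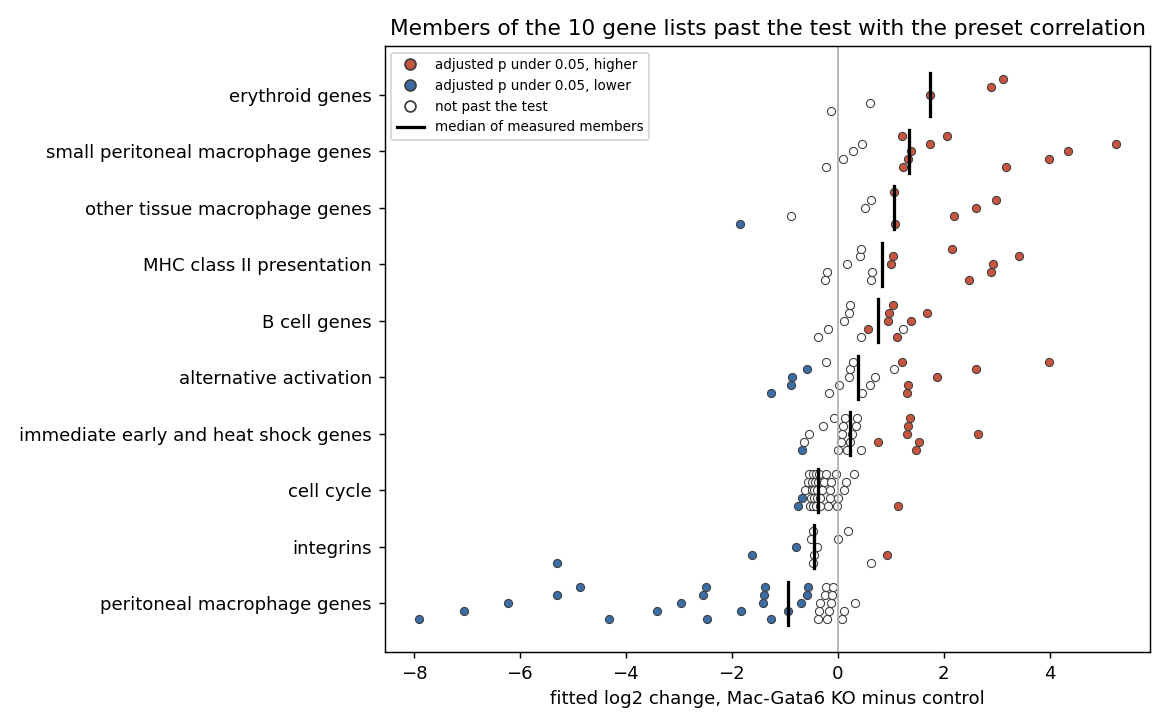
Fitted log2 change (Mac-Gata6 KO minus control, horizontal axis) of each measured member of the 10 lists past the test with the preset correlation, with filled points for members past the test on their own and a bar at the list median. The peritoneal macrophage list has its median at -0.94 with 20 members fallen, and the small peritoneal macrophage list at 1.35 with 10 risen.

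Of the 25 lists tested 10 passed with the preset correlation and 0 with the estimated one, where 5 had an unadjusted p under 0.05. The estimated setting rests on few residual degrees of freedom, so failing it does not by itself count against a list. The preset one assumes its correlation, so passing it does not settle how members vary together. Core macrophage genes did not pass as a list, with 4 risen, 4 fallen and 21 of 29 not passed (adjusted p = 0.777). The Fc receptor Fcgr1 changed by -2.94 ± 0.13, the macrophage surface marker Adgre1 by -1.56 ± 0.17 and Cd81 by -1.49 ± 0.15 on the log2 scale. Gpnmb fell by 2.25 ± 0.22 and was detected on 1 of the 2 knockout arrays.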

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

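Without background correction 1090 genes were higher and 1156 lower, with the authors' values 1100 and 1142, with an intensity trend and robust variance 1089 and 1134, and with a threshold of at least 2-fold 372 and 332. With the estimated correlation 0 lists passed. A higher correlation cannot account for that in every list. The estimate was below the preset 0.01 for small peritoneal macrophage (-0.047), B cell (-0.044) and cell cycle (0.0006) genes, among others. Of the lists that passed, peritoneal macrophage (0.014), class II (0.030) and alternative activation (0.041) had an estimate above 0.01. With an estimated correlation camera refers its statistic to the residual degrees of freedom, which are few with 4 arrays. With the preset one it does not, so p-values differ widely even at a similar correlation. For the peritoneal macrophage list the unadjusted camera p was 2.5e-16 with the preset and 0.016 with the estimated correlation. The cause of other differences between settings was not tested, apart from the fold threshold, which drops smaller changes by construction. Of the 704 genes called with at least 2-fold, between 653 and 704 were called in the same direction in the other settings that kept all 4 arrays. Fold sizes were less stable. Without background correction 167 genes were higher and 154 lower by at least 2-fold, and with the authors' values 175 and 163. Leaving out 1 array, with the lone array of a group assumed to vary like the other group, gave 249 to 390 genes higher, 238 to 416 lower, 6 to 13 lists, and Gata6 log2 changes from -0.91 to -0.63 that no longer passed. Fewer arrays leave fewer degrees of freedom. The filter still required detection on 2 arrays, so a gene detected only in the group left with 1 array was dropped. With 1 array left out the fitted log2 change of Ltbp1 went from -8.14, not a measured size since the knockout side is background, to 0.39. The sign turned without control 2, because its bright probe was then detected on 1 array, failed the filter and gave way to the dim probe, which did not pass. Values were also compared over the named genes and up to 4 members of each list, Gata6 aside. In the settings that kept all 4 arrays, 31 values lost the threshold, 23 crossed it and 1139 kept direction and side. Losses were more frequent with an array left out. A gene with no kept probe in a setting gave no value there and was not counted as a loss.

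The replicate numbers do not pair the samples in the labels, and the deviations of same-numbered arrays correlated at -0.13 across genes, which are not independent. With the replicate block 597 genes were higher and 560 lower, 10 lists passed and the Gata6 log2 change was -0.76 (adjusted p = 0.0385). A crossed pairing, chosen after seeing the data, gave 730 higher and 745 lower. A block for the slide was not run, since none is named. Signal over background limits genes called from 1 group only: 140 of the higher genes were not detected in control and 122 of the lower genes not in the knockout.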

Other observations

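Several lists that did not pass as a whole held members that changed in opposite directions. In eicosanoid synthesis 5 of 15 measured genes rose and 4 fell (camera adjusted p = 0.486). Ptgis and Pla2g7 had log2 changes of -4.89 ± 0.14 and -2.05 ± 0.13, and Cbr2 and the prostaglandin-degrading enzyme Hpgd rose by 3.11 ± 0.13 and 1.40 ± 0.13. In TGF-beta activation and signalling 3 of 18 rose and 3 fell (0.978), with log2 changes of -2.96 for Tgfb2, -2.47 for Thbs1 and 1.002 for the receptor Tgfbr3, which did not pass without control 2. Among retinoid genes 1 of 13 rose and 3 fell (0.486). The retinoic acid-degrading enzyme Cyp26a1 fell by 2.72 ± 0.17 and the retinoic acid-making enzyme Aldh1a2 rose by 2.07 ± 0.15. Among LXR targets and lipid efflux genes 5 of 16 rose and 3 fell (0.2502), with log2 changes of -2.13 ± 0.15 for Lpl and 1.503 ± 0.19 for Abcg1. Coagulation and fibrinolysis genes had 3 risen and 4 fallen of 14 (0.398), with log2 changes of -3.40 for Selp and -1.83 for F5. The 4 fallen genes here and the 3 fallen TGF-beta genes are also members of the peritoneal macrophage list. Apoptosis regulators had 2 risen and 3 fallen of 24 (0.978), with the near-identical paralogs Bcl2a1b and Bcl2a1d at -1.70 and -1.69.

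Other lists also did not pass. Inflammatory cytokines and chemokines had 3 risen and 2 fallen of 19 (adjusted p = 0.0873). In the main normalization Ccl7 was at least 5.34-fold and Ccl2 at least 2.13-fold higher. Complement had 2 and 2 of 12 (0.808), interferon-stimulated genes 2 and 1 of 25 (0.666), chemokine receptors 2 and 1 of 6 (0.0952), and sterol biosynthesis 0 and 0 of 15 (0.353). Monocyte genes had 4 risen and 2 fallen of 13 (0.289). Haptoglobin Hp had a log2 change of -2.85 ± 0.19 and Cd177 of -1.23 ± 0.13. Plac8 rose by 1.36 ± 0.14, and Ccr2, not well above background in control, was at least 1.68-fold higher. Eosinophil and neutrophil genes had 1 risen and 4 fallen of 7 (0.0846), and this list passed in 6 of 15 alternative settings, at adjusted p from 0.0034 to 0.375. The inflammatory list passed in 2 of 15 (0.040 to 0.929) and the chemokine receptors in 2 of 13 (0.029 to 0.519). Dendritic cell genes had 2 risen and 1 fallen of 7 (0.978). With under 5 measured members, T and NK cell genes (1 risen and 1 fallen of 4), mast cell genes (1 risen of 4) and mesothelial and fibroblast genes (1 fallen of 1) were not tested. For the TGF-beta, eicosanoid, apoptosis, core macrophage and dendritic cell lists, and for the untested T and NK cell list, median and mean log2 change differ in sign.

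The tests of the macrophage shift and of the globins below were chosen after the result was seen, while those of the B cell genes, Lyz2 and the neighbouring genes were set before. Lower peritoneal macrophage genes together with higher small peritoneal macrophage genes could come from a change within the cells or from a change in which cells were sorted. Loss of Gata6-expressing macrophages to cells without Gata6 transcript would lower Gata6 as much as the genes that fell most, yet the fall of Gata6 was smaller than that of Ltbp1 by at least 6.59 on the log2 scale. Against Nt5e, whose main probe was measured in both groups, it was smaller by 6.30 (standard error 0.22). This argues against that form of replacement, but not against replacement by cells that still make a probe-binding Gata6 transcript. A larger share of small peritoneal macrophages cannot be told apart from a change within the cells if small ones make probe-binding Gata6 transcript. Whether they do was not measured. If they do not, the Gata6 values above argue against such a share as the only source. With no change within cells, Nt5e at 0.75% of its control signal would leave few large macrophages, and genes such as Timd4 (log2 change -0.08) would have to be made by small ones at a similar level, which was not measured. Among the small macrophage genes 1 of 14 members lay at or below 0, and the log2 changes spanned 5.48, but members with some signal in control macrophages would rise unequally under either.

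Higher B cell genes might reflect B cells carried through the sort. Of 10 measured genes restricted to the B lineage, 4 rose (40%), between the limits set before, which were under 25% against and at least 50% for. Their median log2 change was 0.71. Cd79b, Bank1, Cd22 and Spib were chosen after their values were seen. Cd79b, the brightest that rose, went from 8.70 to 9.68, and Bank1, at 9.57 in control, had a log2 change of -0.19 ± 0.15. A gene with such signal in control could hide a small addition. Cd22 (5.68 in control) and Spib (5.89), which did not pass, lay near background. Of 17 such genes on the array 7 had no kept probe, among them Ms4a1, Pax5 and Ebf1. None of these 7 was detected on a knockout array, so they give no sign of B cell RNA there. A small amount could lie below detection, so B cell RNA in the knockout samples stays open. Expression of the risen genes by the macrophages stays open too.

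Higher globin genes may reflect red blood cells or their RNA. The fitted log2 changes of Hba-a1 and Hbb-bs differed by 0.23, but both were not well above background in control, so this comparison rests on the background level and decides nothing. The fitted log2 change of Hbb-bt, whose main probe was detected on all 4 arrays, was smaller than that of Hba-a1 by 1.37 (standard error 0.24). That pair taken alone missed the prediction of equal changes, but it rests on the background under Hba-a1 too. In control the main Hbb-bt probe was at 6.05 and Hba-a1 at 4.97, and in the knockout at 7.80 and 8.09. From unlike control levels RNA of 1 source would raise the genes unequally, so the pair does not count against 1 source. The other 2 Hbb-bt probes, not detected in control, had larger fitted changes. No explanation is favoured by these values.

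As a hypothesis, the Cre inserted at the lysozyme M locus could lower Lyz2. Its log2 change was 0.063 ± 0.15, and the 95% interval from -0.29 to 0.42 lies just inside the limit of -0.3 set before, which taken alone counts against the hypothesis. After the values were seen, the interval of every Lyz2 probe in the fit over all probes was required to lie above that limit, and none did. The main probe, at 15.17 in control and 15.23 in the knockout, lies near the top of the scale, where a fall could be compressed. The probe at 10.24 in control had a log2 change of -0.39, with an interval from -0.997 to 0.22. The control genotype is not stated, and controls that carry Cre would show no difference, so the hypothesis stays open.

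A further hypothesis was that sequence of another strain around Gata6 and Lyz2 could change neighbouring genes. Of the 170 genes among up to 50 measured on each side, 17 (10%) were called, against 12.02% of 9021 others. The odds ratio was 0.81 (95% interval 0.46 to 1.35, Fisher's exact test, two-sided, p = 0.476). An excess was not seen, but the interval leaves a small one open.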
